A study of Mus musculus with 6 samples.

How the data were processed

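RNA was sequenced from bEnd.3 cells, a mouse brain endothelial cell line, in 2 groups of 3 libraries. One group received mitochondria isolated from MLO-Y4 cells, a mouse osteocyte-like line, suspended in 100 µl of medium, and the control group received the same volume of medium alone. Cells were collected after 24 h. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. Groups were taken from the treatment label of each sample. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

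The deposited table holds, per gene and sample, a count and an FPKM value (fragments per kilobase of exon, scaled to the mapped fragments of the library). Per the file headers, the count columns are raw; they hold whole numbers with a different total in each library. The library totals behind the deposited FPKM values, recovered as ratios to control 1, differed slightly from the count totals (0.930 against 0.918 for mitochondria 2). Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, and the build was GRCm38; their roles and settings are not given in the sources used here. How reads shared between gene copies were counted, and whether counting used strand, are likewise not given, so genes with near-identical copies or antisense partners are uncertain. Of the 30077 gene identifiers in the table, 29991 were found in GENCODE release M21, and 90.5% of all had the same start and end there. Coordinates are those of the deposited table. The table's Gene Ontology (GO) terms were used as given; 1242 tested genes whose term cell was withheld and 1376 with an empty cell were left out of the enrichment background.

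Totals ranged from 59651087 to 65576084 counts per library. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11255 in all. The tests, gene lists, other settings and rule for naming genes were chosen before the data were examined. By that plan the groups were to be compared with limma on log2(FPKM + 1), or with edgeR's quasi-likelihood test in its place if the table held counts. It did, so edgeR 4.0.16 (R 4.3.3; TMM scaling, glmQLFit and glmQLFTest with default settings, group as the only term, two-sided) was the main test and limma 3.58.1 an alternative. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values for genes are from this edgeR test unless another tool is named. Fold changes are log2 of mitochondria over control with a standard error (SE). For edgeR the SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. Levels are CPM, counts scaled to library size with TMM by edgeR, as mean ± SD over 3 libraries. Counts of 11255 genes were simulated from these libraries, with 50 genes changed at each of 4 folds and a small list of further genes shifted slightly. On these, edgeR recovered 32% of genes changed 1.2-fold, 76% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 8.33% of its calls were false. Genes were drawn independently, with depth as the only factor shared within a library. These rates may therefore not hold where genes move together.

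For 44 planned gene lists, limma's camera tested whether the members moved against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 41 lists with at least 4 tested members. Calls are also given with the correlation estimated from these libraries. GO terms of 10 to 300 tested genes were tested with a one-sided Fisher's exact test, higher and lower genes apart. Shares of counts in a single library carry a 95% Wilson interval, which covers counting error only. Single values per library were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

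The genes named in the text were set by rule. They are, per direction, the 10 largest changes among called genes with a mean FPKM of at least 1 and no overlap between the groups, passing over predicted gene models, up to 4 lowest-p members of each list described, and 15 genes named whatever their result. Other genes are named as chosen after their values were seen.

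The other settings set out in advance were DESeq2 1.42.0, limma on log2(FPKM + 1) with pseudocounts of 1, 0.5 and 0.1, limma with TPM, quantile or median-of-ratios scaling, limma without trend or with array weights, median-of-ratios size factors in edgeR, no filter, a mean FPKM of at least 5, the replicate number as a block, and each library left out in turn. For the lists and GO terms, fry, camera on ranks, an unadjusted p under 0.01 and terms of 5 to 500 genes were also run. Chosen after seeing the data were scaling by library totals only, edgeR's bias-adjusted quasi-dispersion, the ribosomal RNA share as a covariate (log2 of the share of CT010467 and Lars2 counts together), removal of structural RNA genes, and removal of both libraries numbered 2. The removal of structural RNA genes left some of them in.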

Results

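Messenger RNA of bEnd.3 mouse brain endothelial cells was profiled 24 h after the cells received either mitochondria isolated from MLO-Y4 osteocyte-like cells or medium alone, with 3 libraries in each group. The series asks how osteocyte-derived mitochondria alter transcription in endothelial cells. The 3 control libraries held 64972081, 65576084 and 64609635 counts, and the 3 mitochondria libraries 63581460, 59651087 and 60710344. Among 4438 genes with a mean of at least 50 CPM, the median coefficient of variation within a group was 3.49%. Libraries of the same group differed by more than counting noise, with chi-square values per gene of 15.2 to 83.3 on counts without TMM scaling. Each was kept as a separate sample, although these values do not show whether the libraries came from separate cultures.

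Cells given mitochondria had higher levels of antioxidant genes such as Nqo1 and Srxn1 and lower levels of Tnc, Thbs1, Ccn1 and Ccn2, which encode secreted proteins. Ribosomal and other structural RNAs also took a larger part of their libraries. In edgeR's quasi-likelihood test, 235 of 11255 tested genes changed, of which 111 rose and 124 fell. The changes were small: the median absolute log2 fold change of the 235 genes was 0.25, 199 of them changed by less than 0.5 on the log2 scale, and 18 changed by at least 2-fold (15 higher and 3 lower). For 21.1% of all tested genes every mitochondria library lay outside the range of the controls, on one side, where chance gives 10% for 3 against 3 libraries. In all, 202 of the changed genes were listed as protein coding.

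The number of called genes depended strongly on the test. DESeq2 called 597 genes and limma on log2(FPKM + 1) called 39, of which 231 and 35 were among the 235. Without control 1, 2 or 3, edgeR called 145, 81 or 68 genes, and without mitochondria 1 or 3 it called 142 or 78, while 233 were called without mitochondria 2. Genes that rose made up 47.2% of the calls. In edgeR with scaling by library totals alone this share was 17.3% (61 of 353). In limma it was 17.9% (7 of 39) on deposited FPKM and 6.10% (20 of 328) on TPM, with the median of all genes at −0.05 and −0.15 log2.

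The largest increases among the named genes were in structural RNAs. Rmrp, the RNA of the RNase MRP ribonucleoprotein (ENSMUSG00000088088, GRCm38 chromosome 4: 43492788 to 43493058), rose from 0.525 ± 0.141 to 2.52 ± 1.10 CPM (SD, n = 3; log2 fold change 2.26, SE 0.36, adjusted p = 0.00921 in edgeR). The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, rose by 1.91 (SE 0.37) and 1.89 (SE 0.34). Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb, rose by 1.76 (SE 0.28) and the mitochondrial ribosomal RNA mt-Rnr1 by 0.77 (SE 0.17; −0.05 with the ribosomal share as a covariate). Reads assigned to the 18S ribosomal RNA locus under the symbol CT010467, chosen after its value was seen, were 2.55 ± 0.855% of control libraries and 5.65 ± 1.6% of mitochondria libraries (SD, n = 3; two-sided exact permutation p = 0.1, the smallest the design allows). Mitochondria 2 held most, at 7.11% (95% Wilson interval 7.10% to 7.12%), and control 2 least, at 1.59% (1.58% to 1.59%). Lars2, the mitochondrial leucyl-tRNA synthetase, rose with them by 1.41 (SE 0.26) and took 0.257 ± 0.0939% and 0.660 ± 0.198% of counts. Within groups Lars2 followed the share of CT010467 with a correlation of 0.9921, so its rise cannot be told apart from that of the ribosomal reads. Adding the ribosomal share, here CT010467 and Lars2 together, to the model as a covariate, an alternative chosen after seeing the data, left 3 called genes. Of the 235 genes 233 kept their direction in that fit, and their median absolute log2 fold change went from 0.25 to 0.24 while their median SE went from 0.0453 to 0.0820. Left-out libraries ended the calls of CT010467 (all but control 1 and mitochondria 1), mt-Rnr1 (all but mitochondria 1), Rn7s1 (control 1, mitochondria 2 and 3), Rn7s2 (control 1), Rmrp (control 2) and Lars2 (control 3, mitochondria 3).

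**Figure D1:**
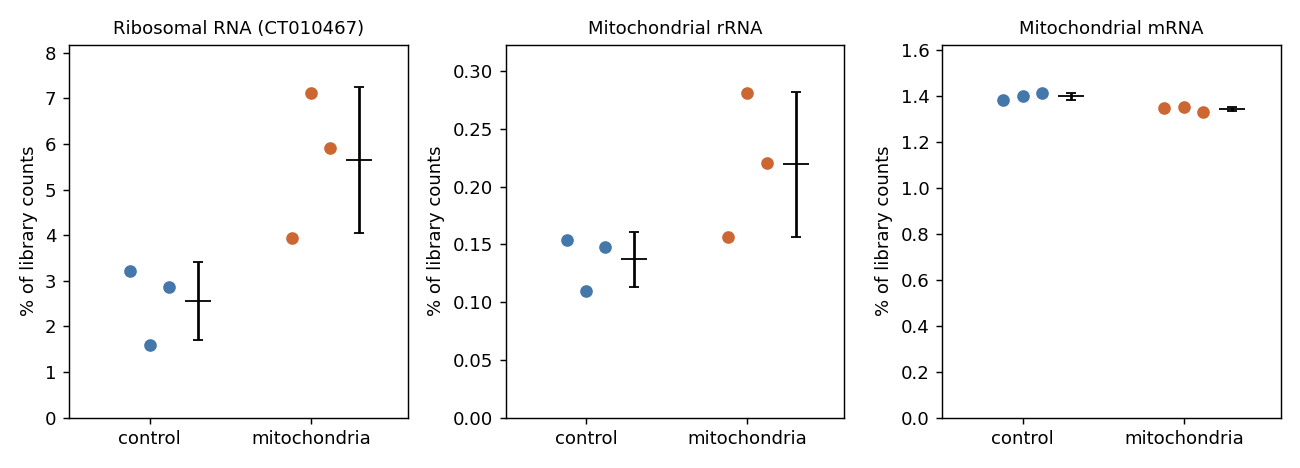
Share of each library's counts (%) taken by the CT010467 ribosomal RNA rows, by mt-Rnr1 and mt-Rnr2, and by the 13 mitochondrially encoded messenger RNAs; points are libraries, black marks are group means with SD (n = 3). Ribosomal RNA runs from 1.59% to 3.21% in control and from 3.94% to 7.11% in mitochondria libraries, while mitochondrial messenger RNA stays between 1.33% and 1.41% in all 6.

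Pnp2, a purine nucleoside phosphorylase gene on chromosome 14, rose from 4.54 ± 0.669 to 12.6 ± 1.10 CPM (SD, n = 3; log2 fold change 1.47, SE 0.15, adjusted p = 0.000499 in edgeR). Gsta1, a glutathione S-transferase, rose by 1.2 (SE 0.21), and Ednrb, the endothelin B receptor, by 1.09 (SE 0.22). The pseudogene Dnajc19-ps rose by 1.34 (SE 0.29) from under 1 CPM. Pnp2, Gsta1 and Dnajc19-ps have close copies in the genome, and how reads were divided among copies is not known. With each library left out in turn, Pnp2 was called in all 6 fits, Ednrb only without mitochondria 1 or 2, Gsta1 not without control 2 or 3, and Dnajc19-ps in none.

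Tnc, which encodes the matrix glycoprotein tenascin C (ENSMUSG00000028364, chromosome 4: 63959785 to 64020725), fell from 389 ± 12.6 to 245 ± 4.72 CPM (SD, n = 3; log2 fold change −0.67, SE 0.04, adjusted p = 2.51e-06 in edgeR), and it alone among the 235 was called in all 19 other analyses set out in advance. Npr3, the natriuretic peptide clearance receptor, fell by 0.61 (SE 0.09), Tll1, a tolloid-like metalloprotease, by 0.52 (SE 0.08), and Bdnf, a neurotrophin, by 0.48 (SE 0.06). Kap fell by 0.63 (SE 0.09) and Lce1g by 0.77 (SE 0.15). Rpl7a, a ribosomal protein gene with many processed copies, fell by 1.25 (SE 0.23), and Phc3, a Polycomb gene, by 1.55 (SE 0.32). For Phc3, control 1 at 27.1 CPM lay close to the mitochondria libraries (21.7 to 23.5 CPM) and far from the other controls at 90.0 and 82.7 CPM, and Phc3 was called in 1 of the 6 fits without a library, that without control 1. Lce1g was not called without control 2 or 3 or mitochondria 2 or 3, nor Rpl7a without control 2 or 3 or mitochondria 3.

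**Figure D2:**
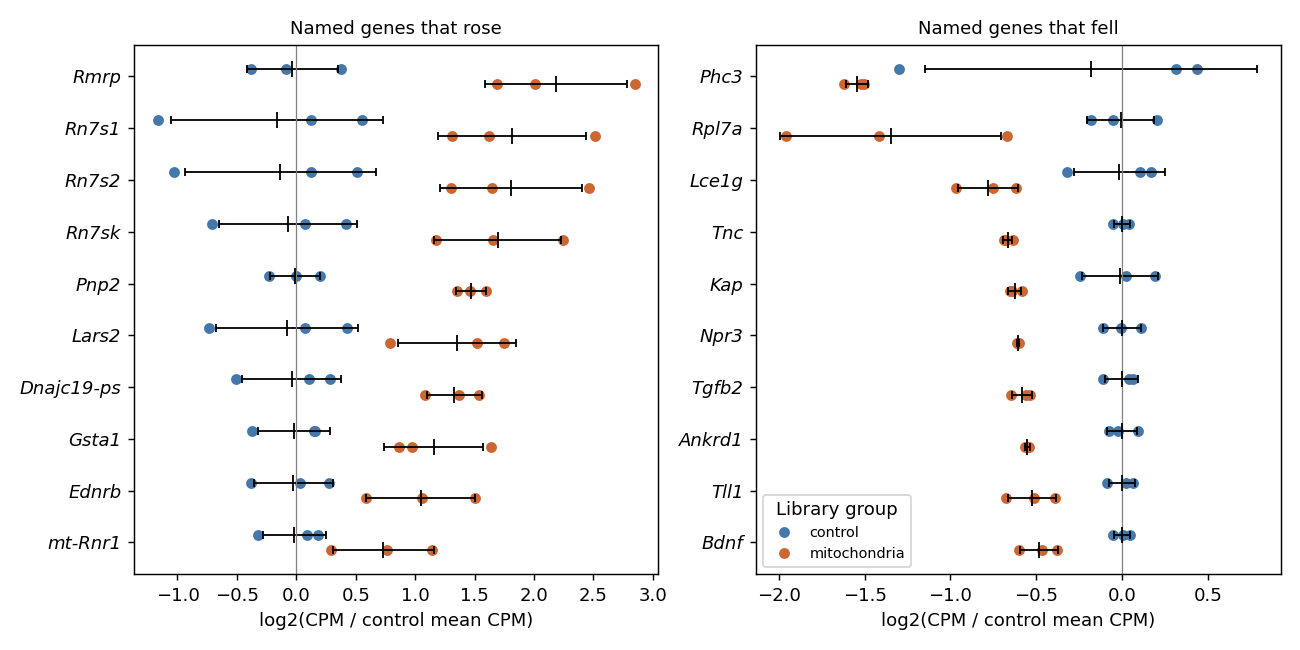
Level of the 10 named genes that rose (left) and the 10 that fell (right) in each library, as log2 of CPM over the mean of the controls; points are libraries, black marks are means with SD (n = 3). No mitochondria library overlaps the controls, but control 1 lies close to them for Phc3, at 27.1 CPM.

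Targets of NRF2, the transcription factor of the antioxidant response, rose as a list. Of 23 tested members, 10 rose, 1 fell and 12 did not pass (15 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.21. Nqo1, a quinone reductase, rose from 179 ± 8.69 to 289 ± 17.7 CPM (log2 fold change 0.69, SE 0.05, adjusted p = 4.75e-05 in edgeR). Srxn1, which reduces oxidised peroxiredoxins, rose by 0.56 (SE 0.05), and the ferritin chains Ftl1 and Fth1, which store iron, by 0.33 (SE 0.03) and 0.27 (SE 0.03). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was the member that fell, from 1899 ± 51.1 to 1673 ± 17.9 CPM (log2 fold change −0.18, SE 0.03), a call lost without mitochondria 3. The list passed camera (adjusted p = 2.05e-16 with the preset correlation, adjusted p = 0.0275 with an estimated correlation) and was the only one of 41 lists to pass with an estimated correlation, against 9 with the preset one.

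YAP/TAZ targets, genes driven by the Hippo pathway's co-activators, were lower. Of 15 tested members, 6 fell, none rose and 9 did not pass (9 fell and 1 rose when adjusted over the list alone), and the median log2 fold change was −0.16. Ccn1 and Ccn2, which encode matricellular proteins, fell by 0.41 (SE 0.03) and 0.33 (SE 0.03). Ankrd1, a cardiac ankyrin repeat gene, fell by 0.55 (SE 0.08), and Tgfb2, a transforming growth factor beta ligand, by 0.58 (SE 0.07). The list passed camera with the preset correlation (adjusted p = 1.83e-08) and not with an estimated one (adjusted p = 0.259 with an estimated correlation). Among GO terms, 1 of 3092 tests passed: actin filament organization held 6 of the fallen genes among 51 tested, where chance gives 0.490 (Fisher's exact test, adjusted p = 0.0259). These were Fat1, Rnd1, Rnd3, Sorbs2, Spire1 and Tpm4, named after their values were seen, with log2 fold changes of −0.28 to −0.16. No GO term passed without mitochondria 2, and 7 did without mitochondria 3. Of the 6 fits without a library, Fat1 was called in none, Rnd1 without control 2 or mitochondria 2, Rnd3 and Spire1 without control 1 or mitochondria 2, Sorbs2 without control 1 or mitochondria 1 or 2, and Tpm4 without mitochondria 1 or 2.

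**Figure D3:**
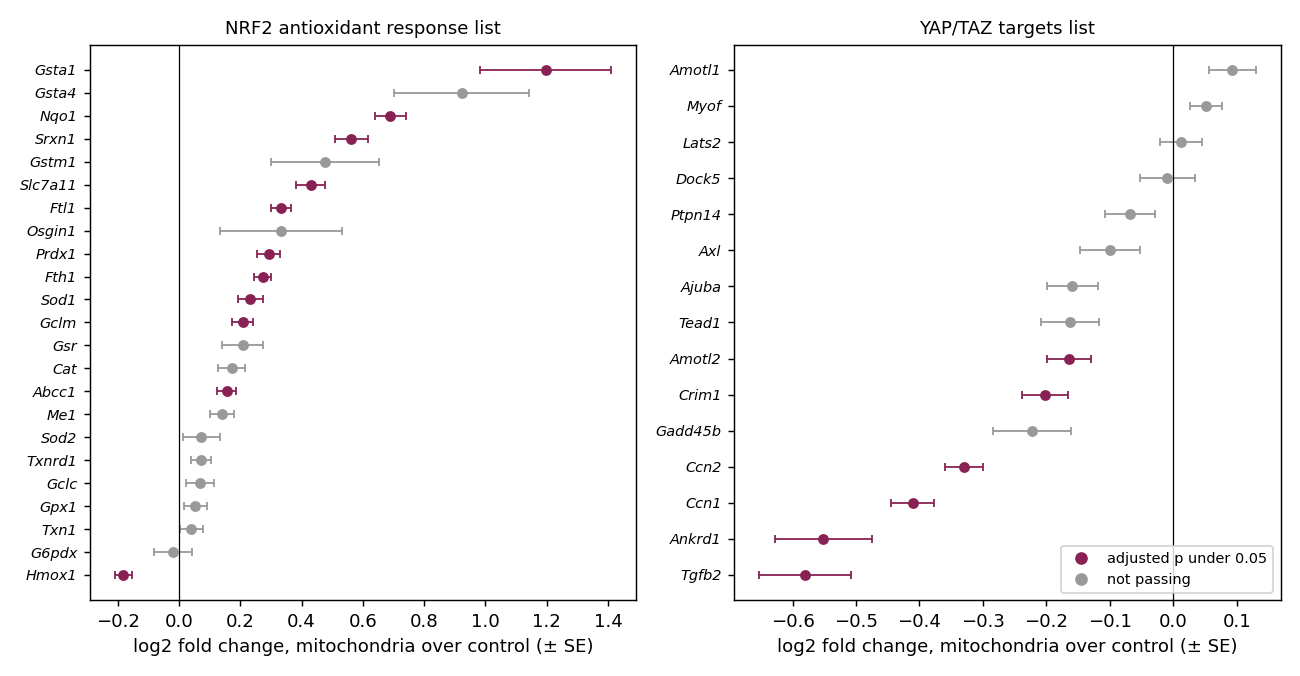
Log2 fold change (mitochondria over control, ± SE, from edgeR with n = 3 per group) of each tested member of the NRF2 list (left, 23 genes) and the YAP/TAZ list (right, 15 genes); coloured points passed an adjusted p of 0.05. In the NRF2 list 10 members rose and Hmox1 fell, and in the YAP/TAZ list 6 members fell.

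Other matrix and growth factor lists held single members that fell and did not pass camera. In the extracellular matrix and basement membrane list 3 of 22 tested members fell and none rose: Col5a2, a fibrillar collagen chain, by 0.31 (SE 0.04), Lamb1, a laminin chain, by 0.22 (SE 0.03), and Fn1, fibronectin, by 0.18 (SE 0.02) (4 fell when adjusted over the list alone). Of the 22 members 9 were above 0, and the median was −0.03 (camera adjusted p = 0.0537, and adjusted p = 0.369 with an estimated correlation). The endothelial-to-mesenchymal transition list held 3 of 15 that fell, which were Tgfb2, Fn1 and Vim, the intermediate filament vimentin (−0.13, SE 0.03). Among TGF-beta and BMP targets, Ccn2 and Bmp4 (−0.30, SE 0.06) fell out of 17. Of 15 immediate early genes only Myc, a growth-promoting transcription factor, passed, with a fall of 0.26 (SE 0.04; 2 fell when adjusted over the list alone). Left-out libraries ended the calls of Vim (all but control 2 and mitochondria 1), Bmp4 (control 1 and 3, mitochondria 3), Myc (control 3, mitochondria 3) and Lamb1 (control 3).

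Interferon-stimulated genes were higher as a list, with 21 of 22 tested members above 0 and a median log2 fold change of 0.26. Of these, 2 rose, 20 did not pass and none fell (6 rose when adjusted over the list alone). Ifit3 rose from 9.75 ± 0.484 to 14.1 ± 1.56 CPM (log2 fold change 0.53, SE 0.12, adjusted p = 0.0427 in edgeR) and Parp14 by 0.49 (SE 0.11). Of the 6 fits without a library, Ifit3 and Parp14 were called only in that without mitochondria 2. The list passed with the preset correlation (adjusted p = 9.35e-07) and not with an estimated one (adjusted p = 0.259 with an estimated correlation). The major histocompatibility class I list behaved alike: its median was 0.16, none of 11 members passed (H2-T22 had the lowest p, at 0.35, SE 0.09, adjusted p = 0.0603 in edgeR; 1 rose when adjusted over the list alone), and camera gave adjusted p = 0.00799 with the preset and adjusted p = 0.259 with an estimated correlation. None of 15 DNA sensing and innate receptor genes passed. In the NF-kappaB and endothelial activation list, Tnfaip3 (−0.41, SE 0.06), which restrains NF-kappaB, Ptgs2 (−0.29, SE 0.05), a cyclooxygenase, and the chemokine Cxcl12 (−0.14, SE 0.03) fell, the adhesion molecule Selp rose (0.24, SE 0.05), and 16 did not pass (3 rose and 4 fell when adjusted over the list alone). Without a library, Cxcl12 was called only without control 1 and Selp only without control 1 or mitochondria 1. Vcam1 had a log2 fold change of 0.15 (SE 0.07, adjusted p = 0.371 in edgeR; −0.014 with TPM), and Icam1 was below the filter, at 0.246 to 0.419 FPKM in the 6 libraries.

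Of the 13 mitochondrially encoded messenger RNAs, mt-Co3 rose (0.17, SE 0.03), mt-Nd5 fell (−0.16, SE 0.03) and 11 did not pass, among them mt-Nd1 (0.07, SE 0.03; −0.09 with TPM and −0.00402 with array weights) and mt-Co1 (−0.02, SE 0.02). Without a library, mt-Co3 was called in 2 of 6 fits (those without control 1 or mitochondria 2) and mt-Nd5 in 1 (that without mitochondria 2). When adjusted over the list alone 1 rose and 2 fell. The list's median was 0.0020, its mean −0.0036, and camera gave an adjusted p of 0.820. Together these transcripts were 1.40 ± 0.0143% of counts in control and 1.34 ± 0.00997% in mitochondria libraries (SD, n = 3; exact permutation p = 0.1). With the counts of CT010467 and Lars2 left out they were 1.44 ± 0.0173% and 1.43 ± 0.0292% (exact permutation p = 0.9). None of 73 nuclear respiratory chain and ATP synthase genes passed, while 50 were above 0 (median 0.04). That list did not pass camera (adjusted p = 0.0578, and adjusted p = 0.818 with an estimated correlation) but passed camera on ranks (adjusted p = 0.0442). No gene passed either in the lists of the tricarboxylic acid cycle (25 tested; 2 rose and 1 fell when adjusted over the list alone), fatty acid oxidation (19), mitochondrial biogenesis and DNA upkeep (18), fusion, fission and transport (17), the mitochondrial unfolded protein response (15; 1 fell when adjusted over the list alone) and mitochondrial ribosomal proteins (44). Tfam, which packages mitochondrial DNA, had a log2 fold change of −0.06 (SE 0.08), and Ppargc1a held 0 to 25 counts per library, below the filter.

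Lists of organelle turnover and glycolysis were slightly higher with the preset correlation. In mitophagy 2 of 19 tested members rose, the autophagy receptor Sqstm1 (0.23, SE 0.04) and Gabarap (0.20, SE 0.04), with a median of 0.05 (camera adjusted p = 0.0101, adjusted p = 0.259 with an estimated correlation). In lysosome and autophagy genes Hexa (0.19, SE 0.04), a hexosaminidase chain, and Sqstm1 rose out of 30, with a median of 0.05 (adjusted p = 0.00745, and adjusted p = 0.519 with an estimated correlation). In glycolysis Aldoa (0.12, SE 0.03) and Pkm (0.11, SE 0.02) rose out of 19, with a median of 0.05 (adjusted p = 0.0279, adjusted p = 0.0765 on ranks, and adjusted p = 0.477 with an estimated correlation). Among hypoxia-response genes Ddit4 (0.40, SE 0.08) and Egln3 (0.32, SE 0.07) rose and Cited2 (−0.24, SE 0.05) fell out of 25, with a median of 0.09 (adjusted p = 0.0101, and adjusted p = 0.781 with an estimated correlation). When adjusted over each list alone, 3 rose in mitophagy, 3 in lysosome and autophagy, 4 in glycolysis, and 3 rose and 1 fell in the hypoxia response. With TPM the medians of these 4 lists fell below 0, as did Aldoa and Pkm. The glycolysis, mitophagy and lysosome medians were also below 0 on deposited FPKM. The median of all genes was itself −0.15 with TPM and −0.05 on deposited FPKM. Of the 6 fits without a library, Aldoa and Pkm were called in none, Ddit4, Egln3 and Cited2 only without mitochondria 1, Hexa only without mitochondria 2, Sqstm1 only without mitochondria 1 or 2, and Gabarap only without control 1 or mitochondria 2. None of 25 endocytosis and macropinocytosis genes passed.

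Thbs1, which encodes the angiogenesis inhibitor thrombospondin 1, fell from 3309 ± 16.1 to 2433 ± 39.0 CPM (SD, n = 3; log2 fold change −0.44, SE 0.02, adjusted p = 2.51e-06 in edgeR). Of the other angiogenesis inhibitors, Timp2 rose (0.25, SE 0.03) and 10 of 12 did not pass, including the VEGF receptor Flt1 (0.25, SE 0.06, adjusted p = 0.0503 in edgeR; 3 of the list rose and 1 fell when adjusted over the list alone). Of 34 sprouting and tip cell genes, the integrin chain Itgb3 rose (0.24, SE 0.04) and none fell (1 rose and 1 fell when adjusted over the list alone). Esm1 was at −0.65 (SE 0.15, adjusted p = 0.0546 in edgeR). Kdr, the main VEGF receptor, was at 0.04 (SE 0.03; −0.03 on deposited FPKM and −0.12 with TPM), and its ligand Vegfa at −0.03 (SE 0.10; 0.06 without mitochondria 1 and 0.01 without control 2). Of 26 endothelial identity genes 1 rose, Sox18 (0.50, SE 0.09), while 22 were above 0 (4 rose and 1 fell when adjusted over the list alone). Pecam1 was at 0.07 (SE 0.03; −0.09 with TPM) and Cdh5 at 0.0033 (SE 0.03; −0.06 on deposited FPKM and −0.16 with TPM). That list's median was 0.06 (camera adjusted p = 0.00349, and adjusted p = 0.477 with an estimated correlation). With TPM it fell below 0, as did the median of all genes (−0.15). Among shear stress and KLF2/KLF4 genes Klf2, a flow-responsive transcription factor, rose (0.30, SE 0.05) and Edn1, endothelin 1, fell (−0.31, SE 0.04) out of 16 (7 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.104). In the blood-brain barrier list the efflux transporter Abcc4 rose (0.25, SE 0.04) and the transferrin receptor Tfrc fell (−0.18, SE 0.04) out of 16 (1 rose and 2 fell when adjusted over the list alone). Left-out libraries ended the calls of Tfrc (all but mitochondria 2), Sox18 (control 2 and 3, mitochondria 1), Abcc4 (control 2 and 3) and Itgb3 (control 3, mitochondria 3). None of 13 Notch genes passed.

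Of 30 tested genes of sphingolipid metabolism and signalling, S1pr1, a sphingosine 1-phosphate receptor, fell from 416 ± 2.82 to 372 ± 10.8 CPM (SD, n = 3; log2 fold change −0.16, SE 0.03, adjusted p = 0.0285 in edgeR) and 29 did not pass (1 rose and 1 fell when adjusted over the list alone). Sphk1, a sphingosine kinase, was at −0.05 (SE 0.12; 0.21 with the ribosomal share as a covariate and 0.04 without control 2). The list's camera adjusted p was 0.502. Of the 6 fits without a library, S1pr1 was called only in that without mitochondria 2. None of 22 cholesterol biosynthesis genes passed.

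Lists of growth, death and stress did not pass camera. No cell cycle gene passed among 44 (median 0.02), with Mki67 at 0.04 (SE 0.07; −0.02 on deposited FPKM, −0.11 with TPM and −0.03 without control 1), and no p53 target among 21 (median −0.05), a list that passed fry (adjusted p = 0.00982) and not camera (adjusted p = 0.0893). Bak1, a pro-apoptotic gene, rose (0.24, SE 0.05) out of 18 apoptosis genes (3 rose and 1 fell when adjusted over the list alone). In the ATF4 integrated stress response Slc7a11 (0.43, SE 0.05) and Slc3a2 (0.21, SE 0.04), the chains of the cystine transporter, and Ddit4 rose out of 26 (3 rose and 2 fell when adjusted over the list alone). The median of that list was −0.01 and its mean was 0.04. No endoplasmic reticulum chaperone passed among 19. Of 17 cytosolic heat shock genes Cryab rose (0.23, SE 0.05) and Hsp90ab1 fell (−0.12, SE 0.03), and 1 rose and 2 fell when adjusted over the list alone. In the list of metallothioneins and zinc response, Hmox1 was the one gene of 4 that passed. Rplp1 rose (0.19, SE 0.04) out of 43 cytosolic ribosomal protein genes. Of the 6 fits without a library, Hsp90ab1 was called in none, Cryab only without mitochondria 3, Bak1 only without mitochondria 2, Rplp1 only without control 1 or mitochondria 2, Ddit4 only without mitochondria 1, and Slc3a2 not without control 2 or 3. Replication-dependent histone genes, whose messages lack a poly(A) tail, had a median of −0.20 with none of 12 passing (camera adjusted p = 0.0586).

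Of 22 osteocyte and osteoblast markers, listed for the donor line, 4 were tested and none passed (median 0.01). These 4, Gja1, Spp1, Ank and Cd44, were at 3.90 to 50.9 FPKM in control libraries, so they do not single out donor material. Below the filter the markers went both ways at low levels. Counts summed over a group were 0 in control and 15 with mitochondria for Pdpn, 31 and 12 for Phex, and 4 and 0 for Sost. These 3 were not tested, and were named after their values were seen. Only 2 of 16 mural and fibroblast markers, 2 of 16 blood and macrophage markers and 1 of 12 neural markers passed the filter. Of these Cd68, a lysosomal glycoprotein used as a macrophage marker, rose from 53.3 ± 2.33 to 78.3 ± 7.89 CPM (SD, n = 3; log2 fold change 0.55, SE 0.07, adjusted p = 0.00212 in edgeR). The other blood and macrophage markers went both ways at low levels: below the filter, summed counts over the 3 libraries of a group were higher with mitochondria for Lyz2 (93 in control and 305 with mitochondria), Fcer1g (5 and 16), Itgam (0 and 12) and Tyrobp (0 and 11). They were lower for Cx3cr1 (52 and 8), Ptprc (17 and 3), C1qb (23 and 6) and Adgre1 (7 and 0). These genes were not tested, and were named after their values were seen.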

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

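Scaling by library totals, the bias-adjusted quasi-dispersion, the ribosomal RNA covariate, removal of structural RNA genes and removal of both libraries numbered 2 were chosen after the results were seen; the other alternatives were planned. edgeR gave 235 changed genes (111 higher, 124 lower, 18 over 2-fold), 9 gene lists and 1 GO term. In every alternative, each gene called both there and by edgeR had the same direction. Of the 235 genes, 52 were called in all 6 fits without a library, and 1, Tnc, in all 19 other analyses set out in advance. Over all alternatives, 1210 values of named genes stayed on their side of the threshold with their direction, 738 lost their call, 14 gained one and 36 changed sign; for the lists called at first, 182 stayed, 42 lost their call and 19 changed sign. All 19 sign changes of lists came from settings where the median of all genes was itself below 0 (−0.05 to −0.15). The NRF2 list stayed above 0 and the YAP/TAZ list below 0 in all alternatives. Unless a reason is given, the cause of a difference was not tested. Depth limits the genes near the filter, and with 3 libraries per group edgeR recovered 32% of simulated 1.2-fold changes.

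DESeq2 gave 597 changed genes (270 higher, 327 lower, 20 over 2-fold), 9 gene lists and 21 GO terms. Median-of-ratios size factors in edgeR gave 237 changed genes (113 higher, 124 lower, 18 over 2-fold), 9 gene lists and 2 GO terms. The bias-adjusted quasi-dispersion gave 243 changed genes (114 higher, 129 lower, 18 over 2-fold), 9 gene lists and 1 GO term. Removal of structural RNA genes gave 237 changed genes (107 higher, 130 lower, 12 over 2-fold), 9 gene lists and 1 GO term. That fit shared 228 of the 235 calls of the main test, although 10 of the 235 were structural RNAs. Some called structural RNAs therefore stayed in, and the fit does not show the result without all of them. Testing 27651 genes with no filter gave 22 changed genes (6 higher, 16 lower, 2 over 2-fold), 13 gene lists and 0 GO terms, with a correction over more genes. A mean FPKM of at least 5 gave 248 changed genes (121 higher, 127 lower, 13 over 2-fold), 9 gene lists and 8 GO terms. The replicate number as a block gave 394 changed genes (184 higher, 210 lower, 20 over 2-fold), 12 gene lists and 22 GO terms. Deviations from the group mean correlated between libraries of the same number by 0.0729, 0.0898 and 0.0606. Those of other pairs ran from −0.183 (control 2 and mitochondria 1) to 0.121 (control 3 and mitochondria 1). With 3 libraries per group these values cannot tell whether the numbers pair the libraries. Removal of both libraries numbered 2 gave 99 changed genes (43 higher, 56 lower, 13 over 2-fold), 7 gene lists and 2 GO terms, with fewer libraries, and Sphk1 at 0.048.

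limma on log2(FPKM + 1) gave 39 changed genes (7 higher, 32 lower, 4 over 2-fold), 6 gene lists and 1 GO term. There the list medians were −0.00884 for glycolysis, −0.000437 for mitophagy and −0.0155 for lysosome and autophagy, and the log2 fold changes −0.0183 for Mki67, −0.0576 for Cdh5 and −0.0257 for Kdr. A pseudocount of 0.5 in limma gave 39 changed genes (7 higher, 32 lower, 5 over 2-fold), 6 gene lists and 1 GO term. There the list medians were −0.00898 for glycolysis, −0.000263 for mitophagy and −0.0160 for lysosome and autophagy, and the log2 fold changes −0.0191 for Mki67, −0.0577 for Cdh5 and −0.0258 for Kdr. A pseudocount of 0.1 in limma gave 36 changed genes (6 higher, 30 lower, 4 over 2-fold), 6 gene lists and 0 GO terms. There the list medians were −0.00909 for glycolysis, −0.000103 for mitophagy and −0.0164 for lysosome and autophagy, and the log2 fold changes −0.0198 for Mki67, −0.0578 for Cdh5 and −0.0259 for Kdr. limma without trend gave 3 changed genes (1 higher, 2 lower, 2 over 2-fold), 6 gene lists and 0 GO terms. There the list medians were −0.00884 for glycolysis, −0.000437 for mitophagy and −0.0155 for lysosome and autophagy, and the log2 fold changes −0.0183 for Mki67, −0.0576 for Cdh5 and −0.0257 for Kdr. TPM in limma gave 328 changed genes (20 higher, 308 lower, 16 over 2-fold), 4 gene lists and 1 GO term. The median of all genes was −0.15 there and −0.05 in limma on log2(FPKM + 1). With TPM the list medians were −0.11 for glycolysis, −0.10 for mitophagy, −0.0925 for endothelial identity, −0.0666 for the hypoxia response and −0.11 for lysosome and autophagy. The log2 fold changes were −0.0872 for Pecam1, −0.0137 for Vcam1, −0.0396 for Aldoa, −0.11 for Mki67, −0.16 for Cdh5, −0.0476 for Pkm, −0.12 for Kdr and −0.0900 for mt-Nd1. Quantile normalization gave 53 changed genes (20 higher, 33 lower, 2 over 2-fold), 12 gene lists and 0 GO terms, with Cdh5 at −0.0146. Median-of-ratios scaling in limma gave 37 changed genes (16 higher, 21 lower, 3 over 2-fold), 11 gene lists and 1 GO term. Array weights gave 252 changed genes (43 higher, 209 lower, 10 over 2-fold), 6 gene lists and 7 GO terms, with lysosome and autophagy at −0.0208, Cdh5 at −0.0377, Kdr at −0.0163 and mt-Nd1 at −0.00402. Library totals alone gave 353 changed genes (61 higher, 292 lower, 17 over 2-fold), 7 gene lists and 22 GO terms, with lysosome and autophagy at −0.000940, Mki67 at −0.0133, Cdh5 at −0.0443 and Kdr at −0.0125.

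The ribosomal RNA share as a covariate gave 3 changed genes (1 higher, 2 lower, 1 over 2-fold), 6 gene lists and 0 GO terms, with Sphk1 at 0.21 and mt-Rnr1 at −0.0480. The share follows the groups (correlation 0.823 for CT010467 alone), so the SE of the 235 genes grew from a median of 0.0453 to 0.0820. Their median absolute log2 fold change went from 0.25 to 0.24, and 233 kept their direction. Without each library in turn there were 68 to 233 changed genes, 30 to 99 higher, 38 to 134 lower, 9 to 18 over 2-fold, 6 to 11 gene lists and 0 to 7 GO terms; the highest count of changed genes was without mitochondria 2 and the lowest without control 3. Over these fits the log2 fold change ranged from −0.0298 to 0.12 for Mki67, −0.15 to 0.0634 for Vegfa, −0.13 to 0.0373 for Sphk1 and −0.0150 to 0.0130 for Cdh5. An estimated correlation left 1 list past the threshold (NRF2), fry 4 (NRF2, YAP/TAZ, interferon-stimulated genes and p53 targets) and camera on ranks 9, with the nuclear respiratory chain list gained and glycolysis lost. Genes at an unadjusted p under 0.01 gave 18 GO terms, and terms of 5 to 500 genes 4.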

Other observations

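The tests on replication-dependent histones, on mitochondrial messenger RNAs and on NRF2 targets outside the aryl hydrocarbon receptor battery were chosen after their results were seen, and the fit with the ribosomal RNA share as a covariate after the data were seen. In the bEnd.3 cells given mitochondria, 3 splicing factor genes of the SR family, a group not among the planned lists and noticed in the table of all genes, fell. These were Srsf3 (−0.21, SE 0.04, adjusted p = 0.0186), Srsf5 (−0.21, SE 0.04, adjusted p = 0.0285) and Srsf7 (−0.23, SE 0.05, adjusted p = 0.0371 in edgeR), each called in 1 of the 6 fits without a library, that without mitochondria 2, and not by limma on log2(FPKM + 1). Srsf1 was at −0.18 (SE 0.04, adjusted p = 0.0579 in edgeR). No splicing term passed among the fallen genes: Fisher's exact test gave an adjusted p of 0.149 for nuclear speck, 0.183 for mRNA cis splicing and 0.193 for RNA splicing. A wider fall of this family may be present: among 17 other tested SR proteins, CLK kinases and related factors 16 were below 0, with a median of −0.1053, although none passed on its own and Srsf9 was at 0.0041 (camera p = 9.08e-07, and p = 0.0349 with an estimated correlation). No technical explanation was tested for this group.

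Ribosomal and other structural RNAs were higher with mitochondria, a pattern noticed in these data. The 12 tested were listed for that pattern and are not the whole class, so their count and median describe it without testing it. Of the 12, 10 rose, with a median log2 fold change of 1.38. The histone messages, which lack a poly(A) tail, had a median of −0.2017 (mean −0.17, SE 0.10). This argues against all RNA without a tail having passed selection alike, provided that the histone reads come from messages without a tail. Each SE of a list mean in this section is taken over the member genes and holds no error between libraries. The 13 mitochondrial messenger RNAs had a median of 0.001955 (mean −0.0036, SE 0.03). Against this, mt-Rnr1 was at 0.77 (−0.05 with the ribosomal share as a covariate) and mt-Rnr2 at 0.71 (adjusted p = 0.0770 in edgeR). This argues against RNA brought in with the organelles as the source of the higher mt-Rnr1 and mt-Rnr2, provided that messenger and ribosomal RNA last alike. A smaller amount of donor RNA is not excluded, since reads of the 2 mouse lines were not told apart. One factor per library, such as the efficiency of selection, could carry these RNAs together: within groups, 6 structural RNAs followed the ribosomal share with a median correlation of 0.9189, past the bound of 0.8 set for it, but a stricter requirement added after that value was seen, a permutation p under 0.05, was missed by their mean over the 6 libraries (r = 0.93, exact permutation p = 0.0556; rho = 0.83, exact permutation p = 0.111; r = 0.60 without control 2 and mitochondria 1). That factor and the treatment cannot be told apart here, since every mitochondria library held more ribosomal RNA than every control, and cytosolic ribosomes carried along with the isolated mitochondria were not tested.

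The NRF2 list was higher with mitochondria. With the ribosomal RNA share as a covariate its median was 0.2046 (mean 0.22, SE 0.04 over genes), against 0.21 without it. The share follows the groups (correlation 0.823 for CT010467 alone). This fit therefore leans on differences within groups and cannot exclude the share as the cause. Single calls ended: Nqo1 stayed at 0.69 while its SE grew from 0.05 to 0.09 (adjusted p = 0.0506 in edgeR). Srxn1 went from 0.56 to 0.46 (adjusted p = 0.266) and Hmox1 from −0.18 to −0.12 (adjusted p = 0.772 in edgeR). Removing the trend with GC content and gene length left a median of 0.2395, against 0.21 before on the same scale. NRF2 targets outside the battery of the aryl hydrocarbon receptor, 15 tested genes, had a median of 0.2076, and 8 of them rose. All 15 were members of the NRF2 list itself, and Hmox1, the member that fell, was left out of them. They show that the rise reached genes outside that battery. They give no separate test of the receptor's activity as the whole cause. Whether that receptor was active alongside is not settled: of 12 other listed targets 5 were tested, with a median of 0.1472, and none passed. Cyp1b1 (0.15), Ugt1a6a (1.115, SE 0.43) and Ugt1a7c (0.31) were above 0, while Tiparp (−0.014) and Nfe2l2 (−0.018) were slightly below. As a list they were under 0.05 only with the preset correlation (camera p = 0.0245, and p = 0.0835 with an estimated one). Cyp1b1 and Nfe2l2, 2 of the 5, were also on planned lists. Ahrr, which encodes the receptor's repressor, was not among the 5 and was called higher, and is named after its value was seen. Whether the medium of the isolated mitochondria, rather than the organelles, was the cause was not tested, since no control received mitochondria-free isolate.

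The YAP/TAZ list was lower with mitochondria with the preset correlation (camera adjusted p = 0.259 with an estimated correlation). Its median was −0.1311 with the ribosomal share as a covariate (mean −0.16, SE 0.05 over genes). That fit cannot exclude the share as the cause, since the share follows the groups. After removing the trend with GC content and gene length the median was −0.1802, which argues against that trend as the whole cause. With the covariate Ccn1 lost its call at −0.35 (SE 0.06, against 0.03 before; adjusted p = 0.183), while Thbs1, outside the list, was at −0.41 (SE 0.04, adjusted p = 0.00913 in edgeR). For both lists, the requirement that the corrected mean lie 2 SE beyond 0.05 was added after the values were seen. A wider fall of SRF and MRTF targets, genes of the actin cytoskeleton, may go with it: 21 tested targets had a median of −0.07952, 16 were below 0 and Tpm1 fell, though without a library only without mitochondria 1 or 2 (camera p = 0.000174, and p = 0.0147 with an estimated correlation). Cell density, which also moves these genes, is not in the labels and was not tested.

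The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 235 changed genes and the highest other split 3, and 1 split, the real one, reached the real count. For higher genes the values were 111 and 2, for lower genes 124 and 1, for changes over 2-fold 18 and 1, and for GO terms 1 and 0, each again reached by 1 split. For gene lists the real split gave 9 and the split of control 1, mitochondria 1 and mitochondria 2 against the rest gave 10, so that 2 splits reached the real count.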
